A study of Caulobacter vibrioides with 12 samples.

How the data were processed

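Total RNA of Caulobacter crescentus NA1000, depleted of ribosomal RNA, was measured by RNA sequencing in 12 libraries: 2 replicate cultures, each sampled before rifampicin and at 1, 2, 4, 8 and 15 min after it. Per the labels' protocols, cultures of 25 mL grew in minimal medium, aliquots of 1 mL were taken at 28 C into an RNA-stabilising reagent, and the libraries of a replicate set were pooled and run on the same sequencing lane. Per the submitters' processing notes Bowtie 0.12.8 was used; the genome build, the counting tool and whether counting used strand are not given in the sources used here.

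The deposited table gives raw read counts per gene and, beside them, RPKM values per gene and library, with the names of both per the file headers. The deposited RPKM values are blank for genes with 24 or fewer counts, the smallest count with a value being 25, and the denominators they imply lie 4.85% to 9.53% above the summed gene counts. Counts were used for the tests and RPKM only as an alternative scale for half-lives. The table has 4077 gene rows, and 1 further row of totals that names no gene was left out of library sizes and tests. All 4077 rows matched the reference gene table of assembly ASM2200v1 by locus tag, which was used for symbols, gene classes, lengths and gene order only, with no coordinates. It classes 3885 rows as protein-coding, 131 as non-coding RNA, 8 as antisense RNA, 51 as tRNA, 1 as signal recognition particle RNA and 1 as RNase P RNA. Rows for ribosomal RNA and tmRNA were not used here. Libraries held 2907858 to 18225934 counts, of which 186472 to 4022594 were in protein-coding genes, so late values of all but abundant genes rest on few counts.

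In the 2 min replicate 2 library 955 of 2401 genes with 30 or more counts equalled replicate 1 exactly, 112 of them with 1000 or more counts. The library was therefore left out of the main values, a departure from the design with 12 libraries that was decided after the data were seen but before its effect on the calls was examined. The fit with all 12 libraries is given as an alternative. With 1 library at 2 min, that sample is assumed to vary like those of the other times.

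Relative changes were tested with edgeR 4.0.16 (quasi-likelihood fit and F test) in R 4.3.3, with time as the only factor, 6 groups and 11 libraries in one fit. TMM factors came from protein-coding genes, and p was adjusted by Benjamini-Hochberg at 0.05 within each comparison. Of the protein-coding genes 3649 passed edgeR's expression filter and 236 did not. Each time was compared with the time before rifampicin, so the comparisons share those libraries and overlaps between them were not computed. TMM sets a weighted trimmed mean over mRNAs to no change, so higher and lower are relative to that reference and are not changes in the share of mRNA counts. The median gene lay at -0.02, -0.40, -0.68, -0.70 and -0.73 on this scale at 1, 2, 4, 8 and 15 min. Gene groups were tested with camera in limma 3.58.1 (preset inter-gene correlation 0.01; log2 CPM with a prior count of 2), adjusted over 21 groups and 5 comparisons together, 105 tests. No group passed with an estimated correlation (0 of 105 in camera, 8 at an unadjusted p under 0.05). The designed groups numbered 26 and were to use gene products as well as symbols, but the gene table gives no products, so 21 were formed from symbols alone, and only 665 protein-coding genes have one. TonB-dependent receptors, transcriptional regulators, two-component signalling and hypothetical proteins could not be formed, and stable non-coding RNA served as the scale.

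The global fall of mRNA is the sum of protein-coding counts over the sum of stable RNA counts (tRNA, signal recognition particle RNA and RNase P RNA), in percent of the same replicate before rifampicin. Half-lives are -1 over the slope of log2 of (count + 0.5) per stable RNA count on minutes from 0 to 8 min, by least squares within each replicate and from the mean of both slopes. They were computed for the 2790 protein-coding genes with at least 50 counts in both libraries before rifampicin, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The SD given is that of the 2 replicate half-lives. Where a gene had 0 counts in each library of a time, a bound against 3 counts per library replaces the fitted fold. Where few counts were left the ratio is given with its exact 95% binomial interval on summed counts and effective library sizes. Overlapping genes, antisense RNA and the near-identical flagellin genes are uncertain, since reads may be shared between them.

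Genes are named by a rule fixed before the data were examined. It takes the 10 highest and 10 lowest at 4 min and the 5 highest and 5 lowest at 1 and 15 min. These are called protein-coding genes that changed in the same direction in both replicates and had a mean count of at least 50 (over the 11 libraries used, where the rule said 12). It adds the 5 longest and shortest half-lives among genes with an R2 of at least 0.8 in both replicates, and up to 4 called members of each group with the largest change at 4 min. Of 20 genes always named, 17 were tested. The other 3, groEL, rpoB and tufA, have no symbol in the gene table. Other names were chosen after their values were seen.

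The test was tested on simulated data: for the comparison of 4 min with the time before rifampicin, over 3649 genes, it called 58% of 100 genes changed 2-fold, 83% of 100 changed 4-fold and 0.145% of unchanged genes. Only these genes were changed, up as often as down and at 4 min alone, with the others at their mean level throughout. In the data 2632 genes were called at 4 min. The simulated rates hold for few and balanced changes and do not give the error rate of the data. In the simulated half-life fit (0 to 8 min, 9 libraries), true half-lives of 0.8, 1.5, 3 and 6 min gave medians of 0.888, 1.51, 3.00 and 5.99 min over 719, 684, 674 and 713 genes. For 0.8 min the median was 0.956 min over 307 genes with fewer counts before rifampicin and 0.841 min over 412 with more. Short half-lives of genes with few counts may thus be fitted too long. Each simulated gene had a single true half-life. The medians do not cover a level that held at first, as for rpsE. Nor do they cover a fall that slowed, as for dnaA (14.1%, 3.03% and 0.746% left per stable RNA at 2, 4 and 8 min). Per the labels' protocols each replicate set was sampled from its own culture over time, so the replicate numbers pair the samples. As a check, deviations from the time means correlated between libraries of the same number with r from -0.01 to 0.10 (median 0.02, 10 pairs), and from 0.00776 to 0.329 over genes with a mean count of at least 200. Between replicates, log2 CPM correlated across genes with r = 0.985 before rifampicin, 0.991 at 1 min, 0.938 at 4 min, 0.845 at 8 min and 0.771 at 15 min.

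Alternatives were median-ratio size factors, protein-coding totals, the stable RNA scale, other count filters, DESeq2 1.42.0, the replicate as a block, only the libraries of the times compared, each library left out in turn. For half-lives they were other time windows, pseudocounts, count minimums, scales and a negative binomial slope, and for groups camera with an estimated correlation and fry, which tests a group against no change where camera tests it against the other genes. Chosen after seeing the data were all 12 libraries as deposited, the 2 min replicate 2 library where it differs from replicate 1, leaving out the 4 min replicate 2 library, a 2-fold threshold and, as the scale of half-lives, RNase P RNA or signal recognition particle RNA alone.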

Results

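RNA was sequenced from Caulobacter crescentus NA1000, a laboratory strain of an aquatic bacterium with an asymmetric division cycle, before and after rifampicin. Rifampicin blocks the start of transcription by RNA polymerase, so no new messages are begun, while polymerases already past the promoter may still finish theirs. The drug was used at 100 ug/mL, and the course covered 0, 1, 2, 4, 8 and 15 min with 2 replicate cultures at each time, 12 libraries in all. Libraries held between 2907858 counts (4 min, replicate 2) and 18225934 counts (before rifampicin, replicate 1). Counts in protein-coding genes ranged from 186472 (15 min, replicate 1) to 4022594. The median protein-coding gene had 354 and 118 counts before rifampicin but 4 counts in each library at 15 min. Stable RNA, here tRNA, the signal recognition particle RNA and the RNase P RNA together, took 70.4% to 96.7% of a library's counts. In the 2 min replicate 2 library, 955 of the 2401 genes with 30 or more counts (39.8%) had exactly the count of replicate 1, against at most 3.41% in any other pair of libraries. That library was left out, so 11 libraries entered each comparison and the 2 min values rest on 1 library with no replicate check.

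The course addresses how fast messenger RNA disappears once the start of transcription is blocked. The share of counts in protein-coding genes fell from 22.1% and 27.2% before rifampicin to 1.46% and 1.62% at 15 min. Per count of stable RNA, 67.2% ± 10.7 (SD, n = 2) of the mRNA was left at 1 min, 54.4% at 2 min (n = 1), 41.2% ± 19.2 at 4 min, 9.22% ± 0.387 at 8 min and 4.76% ± 0.579 at 15 min (n = 2 each). The message of rsaA, which encodes the surface-layer protein that coats the cell, rose from 3.28% and 2.85% of all mRNA counts to 29.2% and 29.0% at 15 min. Its own count per stable RNA was 45.2% ± 1.22 (n = 2) of the level before rifampicin. The 4 min replicates differed widely, with 27.6% of mRNA left in replicate 1 and 54.8% in replicate 2. The latter library held 73.3 tRNA counts per RNase P RNA count against 121 to 205 in the other 10 libraries. Scaled to RNase P RNA alone, the replicates had 27.7% and 33.5% left at 4 min, but scaled to signal recognition particle RNA alone 30.5% and 47.4%. On the RNase P RNA scale the mean fell from 72.6% ± 0.543 at 1 min to 30.6% ± 4.09 at 4 min and 6.37% ± 0.259 at 15 min (n = 2).

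**Figure D1:**
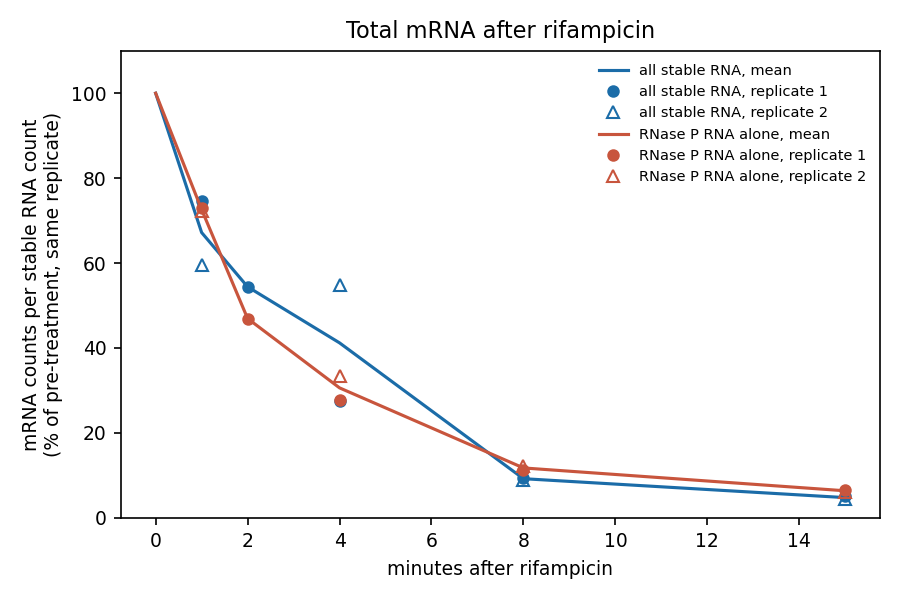
Summed protein-coding counts per count of stable RNA, in percent of the same replicate before rifampicin, against minutes after rifampicin; circles are replicate 1, triangles replicate 2, lines their mean, blue all stable RNA and red RNase P RNA alone. With all stable RNA 4.76% was left at 15 min, and the 4 min replicates stood at 27.6% and 54.8%, which narrowed to 27.7% and 33.5% on the RNase P RNA scale.

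Half-lives were fitted per gene from 0 to 8 min on the stable RNA scale, to rank messages by how fast they fell. The SD covers the 2 replicates and not the choice of time window or scale. Of the half-lives named by rule here and below, 21 moved beyond their SD and 1 changed sign from 0 to 4 min, while 5 did not. From 0 to 15 min 25 moved and 2 did not. On the RNase P RNA scale 15 moved and 12 did not. Scaled to signal recognition particle RNA alone, 10 moved and 17 did not. Late counts were few, as for ctrA with 11 and 28 at 8 min and 17 and 29 at 15 min. Among genes of the cell cycle ctrA, a master transcription regulator of the swarmer cell, had a half-life of 0.970 ± 0.122 min (SD, n = 2), and ftsZ, which forms the division ring, 1.05 ± 0.0279 min. For dnaA, which starts replication, it was 1.10 ± 0.0194 min, and for ccrM, the cell-cycle DNA methyltransferase, 1.298 ± 0.0557 min. The regulator gcrA had 2.69 ± 0.0367 min, above the 90th percentile of all genes (2.66 min). Longer values were 3.38 ± 0.137 min for pilA, the pilus subunit, 5.53 ± 0.368 min for the flagellin fljK, and 7.69 and 16.1 min in the 2 replicates for rsaA. The rsaA values describe a poor line, with an R2 of 0.919 and 0.108, and were 10.998 and 26.7 min on the RNase P RNA scale and -23.19 min, no fall, from 0 to 4 min. The fljK value is uncertain, because reads may be split among the near-identical flagellin genes. Among genes of RNA turnover, rhlB, an RNA helicase of the degradosome, had 1.03 ± 0.107 min and rne, which encodes RNase E, 1.19 ± 0.0348 min. The values were 2.11 ± 0.132 min for pnp, encoding polynucleotide phosphorylase, and 2.30 ± 0.159 min for the aconitase acnA. The remaining messages always named were mipZ (1.20 ± 0.00285 min) and parA (1.10 ± 0.394 min), which place the division site and segregate the chromosome. The others were the polar organizer popZ (1.13 ± 0.0843 min), the sigma factor rpoD (1.31 ± 0.0589 min) and the chaperone dnaK (1.63 ± 0.148 min).

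Over the 2790 protein-coding genes with at least 50 counts in both libraries before rifampicin, the median half-life was 1.40 min (1.42 and 1.41 min in the replicates), with quartiles of 1.20 and 1.75 min. It depended on the fit, being 1.136 min from 0 to 4 min, 2.26 min from 0 to 15 min and 2.246 min with the deposited RPKM. Half-lives were under 1 min for 114 genes and over 4 min for 130 (4.66%), and CCNA_02669 had no fall. Both replicates had an R2 of at least 0.8 in 1817 genes. Of these, the shortest were aimB (0.802 ± 0.177 min), CCNA_02322 (0.812 ± 0.0360 min), divK, a response regulator of cell polarity (0.844 ± 0.000993 min), CCNA_02732 (0.852 ± 0.134 min) and CCNA_01497 (0.853 ± 0.167 min). For divK both 8 min libraries had 0 counts, so that point of the fit is the added count of 0.5 and the small SD is no measure of precision. Among the longest of these 1817 genes were CCNA_00989 (4.42 ± 1.41 min), CCNA_01561 (4.40 ± 0.393 min), CCNA_01480 (4.37 ± 0.0397 min) and CCNA_02378 (4.30 ± 0.0725 min). They are not the top of the range. Genes with longer fitted half-lives, such as rpmD (6.69 ± 0.616 min) and CCNA_02930 (29.2 ± 0.292 min), did not meet the R2 limit. Across genes the slopes of the replicates correlated with r = 0.80 and rho = 0.76, genes not being independent replicates. The half-lives of 158 genes differed over 1.5 times between replicates.

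**Figure D2:**
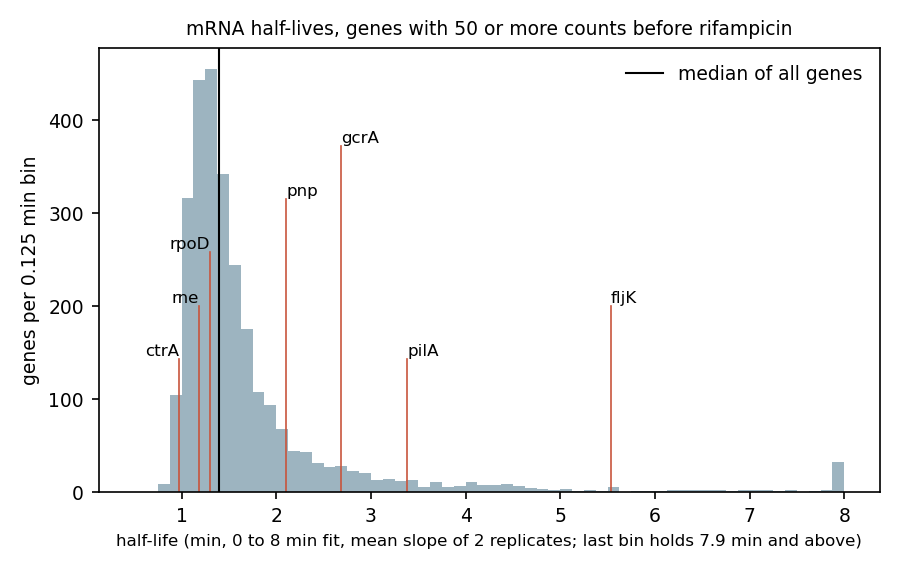
Number of genes per bin of half-life (min, fitted from 0 to 8 min, mean slope of 2 replicates), with the last bar holding half-lives of 7.9 min and above, a black line at the median of 1.40 min and red lines at named genes. From ctrA (0.970 min) to fljK (5.53 min), the named genes span the main body of the distribution and its long tail.

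**Figure D3:**
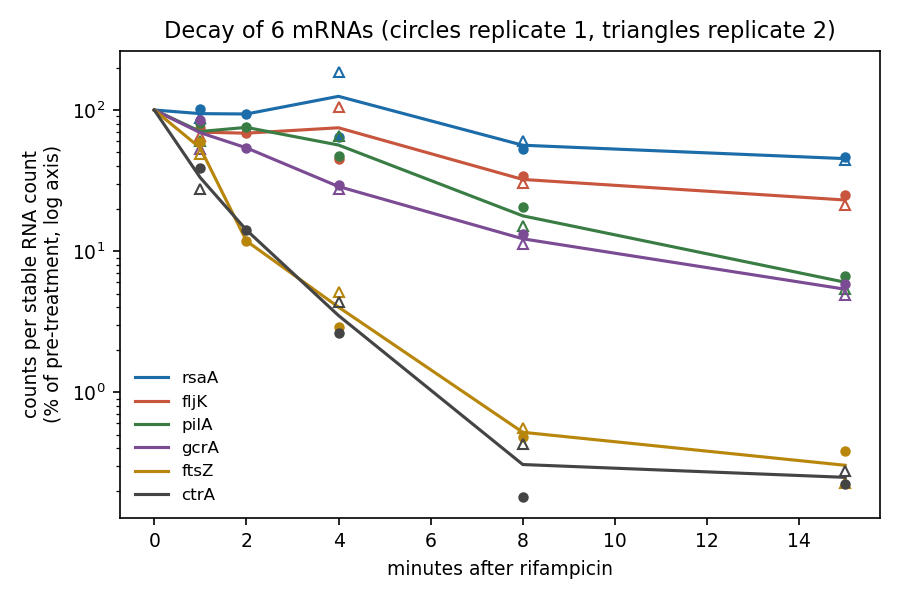
Counts per count of stable RNA of 6 mRNAs, in percent of the same replicate before rifampicin on a log axis, against minutes after rifampicin; circles are replicate 1, triangles replicate 2 and lines the mean. At 8 min ctrA had 0.307% and ftsZ 0.519% left, against 12.2% for gcrA, 17.8% for pilA, 32.2% for fljK and 56.3% for rsaA.

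Gene groups differed in median half-life when set against 10000 random lists of the same size and expression, a description of these libraries with no p-value. The 14 genes of NADH dehydrogenase complex I, which feeds electrons into respiration, had a median of 2.41 min (99.5th percentile), and 26 ribosomal protein genes 1.97 min (96.8th percentile). Random lists ignored gene position, whereas complex I is the nuo cluster and most ribosomal protein genes lie from rpsJ to rplQ. Percentiles of such neighbours may be too extreme. Half-lives were 0.997 to 1.24 min from nuoA to nuoF but 3.19 to 4.42 min from nuoH to nuoN. The complex I median thus joins unlike parts, and so does the ribosomal one, with 1.12 min for rpsJ and 7.96 min for rplO. The 10 fitted chemotaxis genes had 1.66 min (94.4th percentile), and some of them, such as cheYI, cheRI and cheD, also lie near each other by locus tag. At the short end were 6 aminoacyl-tRNA synthetases, which charge tRNA, at 1.05 min (0.13th percentile), 44 genes of flagellum and motility at 1.24 min (0.43rd percentile) and 30 cell cycle regulators at 1.26 min (4.96th percentile). For the 6 synthetases the medians within the replicates were higher, at 1.15 and 1.08 min. Of these 6 genes glyQ and glyS are neighbours by locus tag. The 30 pilus and holdfast genes, with pilA among them, had 1.275 min (7.61st percentile), and the 5 surface layer and export genes, with rsaA, 1.296 min (29.5th percentile).

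The comparison of 4 min with the time before rifampicin asks which messages fell less or more than the TMM reference, a trimmed mean over mRNAs. A gene that is higher in this comparison need not have risen in amount or in its share of mRNA counts. As groups, messages of the ribosome, of complex I and of chemotaxis were higher and those of the cell cycle regulators lower in camera, calls that were lost with an estimated correlation (adjusted p = 0.548, 0.566, 0.320 and 0.320 with an estimated correlation). Complex I genes all lie in the nuo cluster, and most ribosomal protein genes in the cluster from rpsJ to rplQ. Neighbours may move together, so the preset correlation of 0.01 may be too low for these groups. The ribosomal and complex I calls speak largely for those clusters. By locus tag the chemotaxis genes cheYI, cheRI and cheD also lie near each other, so the same limit may hold for that group. The ribosomal protein genes rpsE, rpmD and rpsN were 3.63 ± 0.15, 3.38 ± 0.14 and 3.33 ± 0.14 higher on the log2 scale (± SE), and rsaA was 2.88 ± 0.15 higher (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 8.7e-24, 3.7e-24, 1.8e-23 and 5.7e-21). By contrast ctrA fell by 2.16 ± 0.16, dnaA by 2.49 ± 0.17, ftsZ by 1.97 ± 0.14 and ccrM by 2.61 ± 0.21 (adjusted p = 4.1e-16, 1.2e-17, 1.6e-16 and 3.9e-15, same test). Of 3649 genes tested, edgeR's quasi-likelihood test called 2632 at an adjusted p under 0.05, 972 higher and 1660 lower, and 2249 of them by over 2-fold.

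Other genes with the highest relative level at 4 min were CCNA_01805 (log2 3.81 ± 0.15), CCNA_01164 (3.75 ± 0.13), CCNA_02012 (3.47 ± 0.14), CCNA_03667 (3.43 ± 0.14), CCNA_00434 (3.43 ± 0.51), CCNA_02013 (3.35 ± 0.13) and btuB (3.33 ± 0.15), a gene named for vitamin B12 uptake. CCNA_02012 and CCNA_02013 lie next to the complex I genes, beyond nuoN. The 10 genes with the lowest fitted values were down to 0 to 3 counts per library. CCNA_00036 had 0 counts in both libraries against 499 and 136 before, which places it at least 6.02-fold lower on the TMM scale against a floor of 3 counts per library. For fliJ and flgB, of the flagellar export and rod structures, 1 count was left over both libraries, a fold of 70.8 (95% exact counting interval 12.7 to 2799) and 71.2 (12.8 to 2818). The others were CCNA_02534 (55.9-fold; 9.999 to 2213), CCNA_00691 (52.3-fold; 20.4 to 192), CCNA_00543 (51.2-fold; 17.5 to 248.5), sixA (50.8-fold; 9.08 to 2010), CCNA_03372 (47.2-fold; 16.1 to 229), cleE (40.5-fold; 13.8 to 196.6) and CCNA_02672 (38.6-fold; 13.2 to 187.4); such intervals cover counting error only.

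Among the genes always named, pnp (2.26 ± 0.13), fljK (2.19 ± 0.13), pilA (1.90 ± 0.13), rpoD (1.55 ± 0.13), acnA (1.49 ± 0.13), gcrA (1.05 ± 0.17) and dnaK (0.96 ± 0.14) were higher at 4 min in the edgeR test. By the same test rhlB fell by 2.41 ± 0.21, mipZ by 1.62 ± 0.21 and popZ by 1.14 ± 0.17, and the largest adjusted p of these 10 genes was 4.8e-07. The value of rne was 0.28 ± 0.13 (adjusted p = 0.0480, edgeR), a call that was lost without the 4 min replicate 2 library (adjusted p = 0.115) or without either library from before rifampicin (0.150 and 0.149). The parA value of -0.30 ± 0.25 did not pass the test (adjusted p = 0.288, edgeR). Per count of stable RNA each gene in this paragraph had a negative value at 4 min, and on protein-coding totals dnaK (-0.42), rne (-1.09) and gcrA (-0.29) were negative too.

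Among the gene groups at 4 min, 21 of 26 ribosomal protein genes were higher and 3 lower, with a median of 2.82 (camera, adjusted p = 7.3e-09; adjusted p = 0.548 with an estimated correlation). The same 21 and 3 were the counts when p was adjusted over the list alone. Per stable RNA the ribosomal median was 0.26, with 6 of the 26 genes lower in edgeR's test. Of the 14 complex I genes, 11 were higher and 3 lower, both over all genes and adjusted over the list alone (median 2.34; camera adjusted p = 0.00124; adjusted p = 0.566 with an estimated correlation; median -0.24 per stable RNA). At opposite ends of that group were nuoK and nuoL (both 2.81) and nuoA, which fell by 3.12. Of 13 chemotaxis genes 10 were higher and 1 lower, also adjusted over the list alone (median 1.92; camera adjusted p = 0.00129; adjusted p = 0.320 with an estimated correlation; median -0.80 per stable RNA). The chemotaxis genes cheRI (3.21), cheD (2.93) and cheYI (2.88) were higher, and cheRIII had 2 counts left, 38.9-fold lower on the TMM scale (95% exact counting interval 10.7 to 321.8). Of 30 cell cycle regulators 4 were higher and 23 lower (4 and 24 adjusted over the list alone), with a median of -1.44 (camera adjusted p = 0.00595; adjusted p = 0.320 with an estimated correlation). Those furthest down were perP (22.5-fold, interval 9.59 to 69.3), divK (13.6-fold, 7.35 to 28.3) and rcdA (7.42-fold, 4.01 to 15.5), whereas parB was 2.81 higher.

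The remaining groups did not pass camera at 4 min, and their counts are those of edgeR's test over all genes. The counts adjusted over the list alone were the same unless given. Of 46 flagellum and motility genes 9 were higher and 31 lower (9 and 32 adjusted over the list alone), with a median of -1.83 (camera adjusted p = 0.369). In that group motA, a stator gene, was 18.6-fold lower (interval 10.1 to 38.9). Of 24 toxin-antitoxin genes 0 were higher in edgeR's test (1 at an unadjusted p under 0.05) and 17 lower (median -2.12, camera adjusted p = 0.0605). Of these relB-1 was 21.8-fold (3.87 to 864) and phd 11.1-fold (4.299 to 40.8) lower. Pilus and holdfast genes had 7 of 30 higher and 20 lower (median -1.45, adjusted p = 0.339). The gene hfaA was 24.4-fold lower (8.33 to 118.8) and hfaB 19.3-fold lower (9.36 to 48.2). Of 6 aminoacyl-tRNA synthetases 1 was higher and 4 lower (median -1.70; adjusted p = 0.339), glyQ by 16.6-fold (9.45 to 32.1) and lysS by 3.03 on the log2 scale. Genes of cell division and envelope growth had 5 of 25 higher and 15 lower (median -0.80; adjusted p = 0.455), with pal 2.53 higher and ftsQ down by 2.33. Of 7 protein secretion genes 2 were higher and 5 lower (median -0.43; adjusted p = 0.738), among them secY at 1.43 and bamD at -2.74. Both translation factors, prfC and lepA, were lower (median -1.26; adjusted p = 0.369).

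Groups with a positive median at 4 min included ATP synthase, 2 of 2 higher (median 1.66, camera adjusted p = 0.0989). Fatty acid and lipid synthesis had 4 of 5 higher and 1 lower (median 1.68, camera adjusted p = 0.0504), and so had the TCA cycle (1.49 and 0.0799). Per stable RNA the 3 medians were -0.90, -1.04 and -1.08. Examples were atpD (2.41) and sucB (2.96), while lpxC fell by 2.16 and sdhC by 2.08. Of 6 RNA decay genes 4 were higher and 2 lower, with a median of 0.75 but a mean of -0.01 (camera adjusted p = 0.364). The RNA decay median was negative on protein-coding totals (-0.61) and per stable RNA (-1.86). The surface layer group had 3 of 5 higher and 2 lower (median 0.39, adjusted p = 0.618), or medians of -0.98 on protein-coding totals and -2.11 per stable RNA. Its genes split between rsaA and the exporter gene rsaFa (1.21), which were higher, and rsaFb (-1.32) and rsaD (-1.27), which were lower. Terminal oxidases and cytochromes had 5 of 13 higher and 2 lower (median 0.10; adjusted p = 0.339; -1.25 and -2.59 on those scales), coxC being 2.38 higher. In 4 groups camera's direction was up although median and mean were negative, and none passed. DNA repair and SOS had 4 of 14 higher and 6 lower (median -0.65, camera adjusted p = 0.898), and RNA polymerase and sigma factors 5 of 12 higher and 6 lower (-0.56, 0.898). Amino acid biosynthesis had 10 of 23 higher and 11 lower (-0.15, camera adjusted p = 0.573), and chaperones and ATP-dependent proteases 6 of 12 higher and 6 lower (-0.09, 0.631). With median-ratio size factors the last 2 medians were positive, at 0.05 and 0.10. In these groups imuA (1.69), rpoA (2.34), metE (3.06) and clpP (2.23) were higher, and uvrD (-1.597), nusG (-3.02), dapA (-3.60) and clpS (-1.67) lower.

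**Figure D4:**
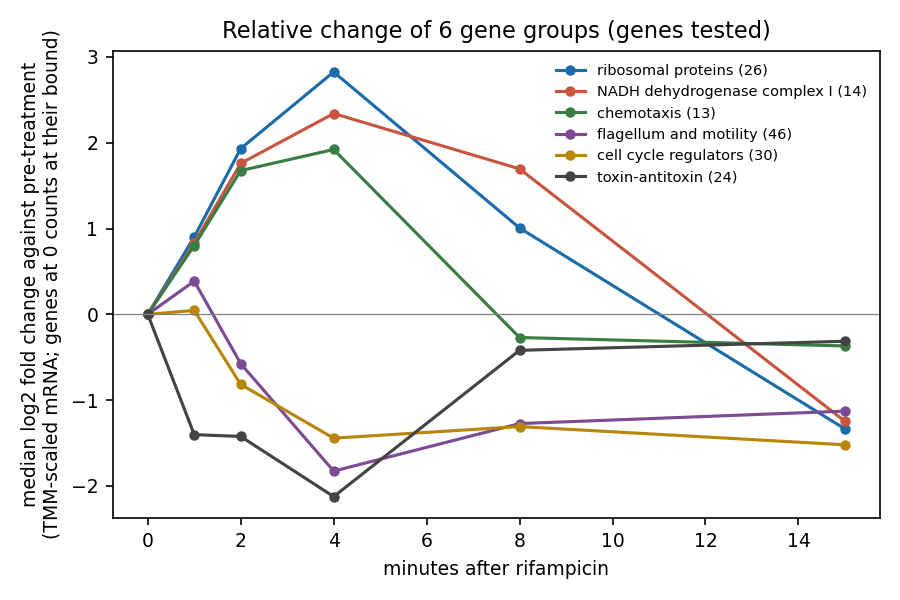
Median log2 fold change against the time before rifampicin of 6 gene groups (number of genes tested in brackets), relative to TMM-scaled mRNA with genes at 0 counts set to their bound, against minutes after rifampicin; the 2 min values rest on 1 library. The ribosomal median reached 2.82 at 4 min and -1.34 at 15 min; per stable RNA, the 4 min medians of complex I (-0.24) and chemotaxis (-0.80) were negative.

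Higher and lower depend on the scale in this comparison. At 4 min protein-coding totals gave 407 higher and 2616 lower genes, and the stable RNA scale 2 higher and 3099 lower (edgeR; 2 higher at an unadjusted p under 0.05). The 2 were CCNA_01805 (log2 1.25, adjusted p = 0.0237) and CCNA_01164 (1.15, adjusted p = 0.0281), in the libraries whose 4 min replicate 2 stands apart in tRNA. The shift of each gene from its TMM value had a median at 1, 2, 4, 8 and 15 min of -0.92, -1.91, -2.81, -5.02 and -5.92 on the stable RNA scale. This median shift was -0.33, -0.82, -1.35, -1.603 and -1.57 on protein-coding totals and -0.07, 0.13, 0.20, 0.22 and 0.29 with median-ratio size factors.

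The comparison of 1 min with the time before rifampicin asks which messages move at once. Toxin-antitoxin messages were the group that fell at this time. Of these 17 of 24 were lower and 0 higher in edgeR's test, over all genes, adjusted over the list alone and at an unadjusted p under 0.05, with a median of -1.40 (camera adjusted p = 0.00169; adjusted p = 0.548 with an estimated correlation). The median half-life of the 15 toxin-antitoxin genes that were fitted was 1.41 min, at the 38.9th percentile of random lists. By that measure the group was not at the short end. The antitoxin gene relB-4 fell by 4.24 ± 0.37. The genes of unknown name CCNA_03372, CCNA_02534, CCNA_02672 and CCNA_03955 had values of -4.88 ± 0.23, -4.01 ± 0.33, -3.94 ± 0.22 and -3.72 ± 0.22 (edgeR, largest adjusted p = 1.2e-12). In the same minute ctrA fell by 0.70 ± 0.13, ccrM by 1.02 ± 0.12 and mipZ by 0.58 ± 0.12, while dnaA (0.02), ftsZ (0.01), popZ (0.07) and rhlB (0.20) did not pass the test. Ribosomal protein genes were higher in 22 of 26 and lower in 2 (median 0.90; camera adjusted p = 3.0e-07), complex I in 12 of 14 and lower in 1 (0.83; 6.6e-05) and chemotaxis in 9 of 13 (0.80; 0.00155). Adjusted over the list alone in edgeR's test the counts were 22 and 2, 13 and 1, and 9 and 0 (0 lower at an unadjusted p under 0.05). The adjusted p with an estimated correlation was 0.548, 0.548 and 0.320 in camera, and the medians per stable RNA were -0.03, -0.10 and -0.13.

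At 1 min the highest relative levels were those of CCNA_03128 (1.20 ± 0.22), CCNA_01553 (1.20 ± 0.16), CCNA_03676 (1.17 ± 0.20), qoxC, a quinol oxidase gene (1.17 ± 0.24), and scpA, a chromosome condensation gene (1.15 ± 0.14; edgeR, largest adjusted p = 4.5e-05). Of the genes always named, parA (0.83), rsaA (0.82), rpoD (0.79), pnp (0.77), rne (0.69) and acnA (0.55) were higher with an adjusted p of at most 2.0e-04 in edgeR's test, and each had a negative value per stable RNA. The smaller values of pilA (0.39; adjusted p = 0.00742), fljK (0.38; 0.00970) and dnaK (0.35; 0.0190) were lost in edgeR's test when 1 library was left out. For pilA this was so without replicate 1 from before rifampicin (adjusted p = 0.0969) or replicate 2 at 1 min (0.0740). For fljK it was so without replicate 1 (0.0729) or 2 at 1 min (0.0598) or replicate 2 from before (0.149), and for dnaK without any one of the 4 libraries (0.0795 to 0.147). The gcrA value of 0.35 missed the threshold (adjusted p = 0.0532) and passed with the replicate as a block (0.34; adjusted p = 0.0123, edgeR). In all 2114 genes were called at 1 min, 1038 higher and 1076 lower (680 by over 2-fold). On protein-coding totals edgeR called 517 and 1508, and on the stable RNA scale 0 and 1482 (0 higher at an unadjusted p under 0.05). With all 12 libraries as deposited edgeR called 427 genes, 20 higher and 407 lower.

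At 2 min, with 1 library, ribosomal protein, complex I and chemotaxis genes were higher as groups in camera, and at 8 min the ribosomal protein genes, calls lost with an estimated correlation. Ribosomal protein genes were higher in 22 of 26 at 2 min (median 1.93; camera adjusted p = 1.5e-08; 0.548 as adjusted p with an estimated correlation) and in 18 of 26 at 8 min (median 1.01; 0.00242; 0.600), with 2 and 7 lower and the same counts adjusted over the list alone. Complex I genes were higher in 12 of 14 and lower in 2 at 2 min, also adjusted over the list alone (median 1.76; camera adjusted p = 1.8e-04; adjusted p = 0.548 with an estimated correlation). Chemotaxis genes were higher in 10 of 13 and lower in 1, again also over the list alone (1.67; 0.00155; 0.320). Per stable RNA the ribosomal median was 0.01 at 2 min and -4.05 at 8 min (-0.61 on protein-coding totals), and those of complex I and chemotaxis at 2 min were -0.16 and -0.23. The 24 toxin-antitoxin genes had a median of -2.56 at 2 min, or -1.42 with the 6 members at 0 counts set to their bound. In camera this group missed the threshold, also with an estimated correlation, and passed with the replicate as a block. At 2 min 2473 genes were called, 1052 higher and 1421 lower. The numbers were 501 and 2103 on protein-coding totals and 2 and 2428 on the stable RNA scale (4 higher at an unadjusted p under 0.05, edgeR). Those 2, named after their values were seen, were CCNA_01484 (log2 1.80, adjusted p = 0.00899) and CCNA_03087 (1.6001, adjusted p = 0.0322). At 8 min 1970 genes were called, 694 higher and 1276 lower. The numbers at 8 min were 287 and 2703 on protein-coding totals, 807 and 970 with DESeq2, and 1 and 3596 on the stable RNA scale (1 at an unadjusted p under 0.05, edgeR). That gene was CCNA_00434 (log2 1.19, adjusted p = 0.0178), a call that rests on 42 and 115 counts before rifampicin. These lie far apart per stable RNA count (13799377 and 3489224 in the 2 libraries), and its replicate values with TMM were 8.24 and 5.48 at 8 min.

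By 15 min ribosomal protein and complex I messages were lower as groups in camera, calls lost with an estimated correlation. The 10 genes with the most counts held 54.7% and 55.0% of the mRNA counts, against 8.30% and 7.82% before rifampicin. Ribosomal protein genes were lower in 22 of 26 and higher in 1 (23 and 1 adjusted over the list alone; median -1.34; camera adjusted p = 0.00408; adjusted p = 0.615 with an estimated correlation). Complex I genes were lower in 13 of 14 and higher in 0 in edgeR's test, the same adjusted over the list alone and at an unadjusted p under 0.05 (median -1.25; camera adjusted p = 0.00903; adjusted p = 0.587 with an estimated correlation). The message of rsaA was 4.83 ± 0.17 higher on the TMM scale, fljK 3.85 ± 0.14, pilA 1.92 ± 0.14 and gcrA 1.75 ± 0.19 (edgeR, largest adjusted p = 3.3e-16 for the first 3 and 7.7e-11 for gcrA). Each was negative per stable RNA (-1.15, -2.13, -4.08 and -4.23). The highest were CCNA_01854 (5.80 ± 0.21), CCNA_00434 (5.76 ± 0.49), CCNA_02930 (5.47 ± 0.16), CCNA_01231 (5.45 ± 0.15) and CCNA_01035 (5.25 ± 0.15), with -0.05, -0.80, -0.51, -0.56 and -0.72 per stable RNA. Before rifampicin CCNA_00434 had 42 and 115 counts in the replicates, the larger number in the library with fewer reads.

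The 5 genes with the lowest fitted values at 15 min had 0 counts in both libraries, so only bounds against 3 counts per library can be given. They were at least 4.72-fold (cleE), 3.04-fold (CCNA_01424), 2.82-fold (CCNA_03919), 2.61-fold (flgB) and 2.52-fold (CCNA_01899) lower on the TMM scale. Of the genes always named, pnp (0.60 ± 0.15) and acnA (0.54 ± 0.14) were higher, and both were negative on protein-coding totals (-0.98 and -1.04) and per stable RNA (-5.40 and -5.45). Lower were ctrA (-2.63 ± 0.23), ftsZ (-2.42 ± 0.20), rhlB (-2.14 ± 0.33), ccrM (-2.09 ± 0.31), rne (-1.92 ± 0.21), dnaA (-1.90 ± 0.21), mipZ (-1.46 ± 0.35), rpoD (-1.44 ± 0.24), popZ (-1.42 ± 0.28) and dnaK (-0.94 ± 0.20), the largest adjusted p being 7.1e-04 (edgeR). The parA gene, with 0 and 3 counts left, was 7.03-fold lower (95% exact counting interval 2.40 to 34.1; edgeR adjusted p = 0.00130). Without replicate 1 at 15 min its log2 value moved from -2.83 to -1.835 and the call was lost (edgeR adjusted p = 0.0781). In all 1619 genes were called at 15 min, 522 higher and 1097 lower. The numbers at 15 min were 221 and 2683 on protein-coding totals, 611 and 770 with median-ratio size factors, 670 and 660 with DESeq2 and 0 and 3624 on the stable RNA scale (0 higher at an unadjusted p under 0.05, edgeR). Tested genes at 0 counts in each library of a time numbered 317 at 2 min, 53 at 4 min, 197 at 8 min and 228 at 15 min.

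Across the whole course edgeR's quasi-likelihood F test called 3211 of 3649 genes. Among complex I genes, those at the start of the cluster were at low levels before those further along, though the values did not follow gene order throughout. At 1 min nuoA had 26.0% ± 2.75 (SD, n = 2) of its level per stable RNA left, and nuoB 63.2% ± 5.86. At 2 min nuoB was at 18.4% and nuoC at 53.3% (n = 1). At 4 min nuoC was at 8.39% ± 5.20 and nuoD at 28.3% ± 14.4, and at 8 min nuoF was at 1.10% ± 0.518 while nuoK still had 27.0% ± 1.83 and nuoN 23.6% ± 1.615 (n = 2). By 15 min nuoN, the last of them, was at 1.23% ± 0.0420. In the ribosomal protein cluster rpsE stood at 125.2% and 277.5% per stable RNA at 4 min, or 125.5% and 169.7% per RNase P RNA, and at 1.20% ± 0.241 per stable RNA at 15 min (n = 2). For genes with such a course a half-life from a straight line describes the fit, not a constant rate of decay.

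**Figure D5:**
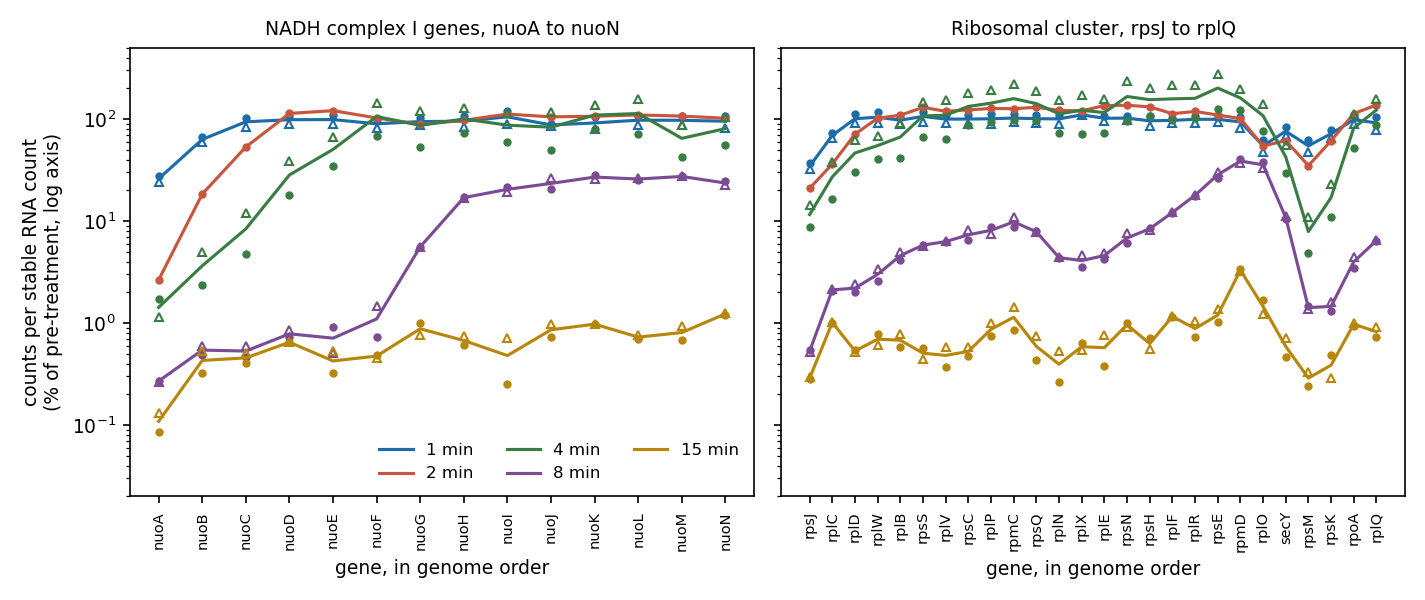
Counts per count of stable RNA, in percent of the same replicate before rifampicin on a log axis, for complex I genes nuoA to nuoN and for the ribosomal protein cluster rpsJ to rplQ in genome order; colours are minutes after rifampicin, circles replicate 1, triangles replicate 2 and lines the mean (1 library at 2 min). At 8 min nuoF had 1.10% and nuoK 27.0% left.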

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

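All tests on the 2 min and 4 min libraries in this part except the slope of the 4 min change were chosen after the result was seen. Outside the comparisons of protein-coding genes, 88 of the 139 rows of non-coding and antisense RNA were above 3 counts in all 11 libraries used, a signal in rows that no comparison analysed. Their values are given with the other observations, and antisense rows share reads with their partner genes where strand was not used.

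In the 2 min replicate 2 library, counts of many genes repeat those of replicate 1. Chance is argued against by the percentage of equal genes, 39.8% of those with 30 or more counts against at most 3.41% in any other pair of libraries. Replicate 1 counts entered for part of the rows is a candidate explanation: stable RNA counts in the equal rows over the other rows gave 0.333 in this library, outside the 0.720 to 0.828 of the other 10, while replicate 1 gave 0.785. Among unequal genes with 30 or more counts the median ratio of replicate 2 to replicate 1 was 3.45, and 80.7% of neighbouring genes were alike in being equal or not, against 53.2% by chance. No biological explanation was tested, and where the repeated counts entered the table stays open.

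At 4 min, replicate 2 had 54.8% of mRNA left per stable RNA and replicate 1 27.6%. Slower decay in the replicate 2 culture predicts smaller relative changes there. The orthogonal slope of its changes on those of replicate 1 was 1.08 (bootstrap interval over genes 1.05 to 1.10, 1062 genes), which shows no such reduction. This slope takes noise as equal in both replicates. Replicate 2 had fewer protein-coding counts, 1345839 against 4022594 before rifampicin and 491721 against 806277 at 4 min. The added noise may raise the slope, so it cannot decide on slower decay. Low recovery of tRNA in this library may account for part of the gap, since tRNA per RNase P RNA was 73.3 against 121 to 205 in the other 10 libraries, and against RNase P RNA the replicates differed 1.21 times. Against signal recognition particle RNA, which holds no tRNA either, they still stood at 30.5% and 47.4%, and tRNA per signal recognition particle RNA was 29.9 against 33.2 to 40.3 in the other 10. The stable RNAs thus gave different answers, and the source of the gap stays open.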

How the results depend on the processing

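Alternatives chosen after seeing the data are marked as added. Scales from ribosomal RNA and tmRNA were not run, since such rows were not used here. Of 124 alternatives of the counts of genes, half-life median, mRNA left and gene groups, 93 stayed near the main result. Near means within a fixed ratio for counts, and within the replicate SD for half-lives and mRNA left (any difference counted at 2 min). The SD of the half-life median was 0.00367 min, so even 1.405 min counted as moved. Of 1690 values of named genes 1465 were the same, 62 lost their call, 6 gained one, 123 moved and 34 changed sign. Genes named only as group members were left out. A change not called in the main fit counted as the same where its sign turned. Depth limits the late times: the lowest library, at 15 min, had 186472 protein-coding counts, and fitted folds of genes at 0 counts lie far above the bounds from their counts. The stable RNA, protein-coding total and TMM scales ask different questions, by construction.

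At 1 min 427 genes were called with all 12 libraries as deposited (added; the cause was not tested) and 680 with a 2-fold threshold (added), against 2114. Protein-coding totals called 2990 genes at 8 min and 2904 at 15 min, and the stable RNA scale 3597 and 3624. With only the libraries of the times compared, 15 min gave 613 higher and 501 lower genes, against 522 and 1097. Leaving out 1 library at a time gave 1555 to 1793 genes at 1 min, 2268 to 2327 at 2 min, 2126 to 2491 at 4 min, 1411 to 1826 at 8 min and 1125 to 1521 at 15 min.

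The median half-life of 1.40 min was 1.136 min from 0 to 4 min, 2.26 min from 0 to 15 min and 1.544 min from 1 to 8 min, 2.246 min with the deposited RPKM, 1.363 and 1.52 min with a smaller pseudocount and one of 2, and 1.466 and 1.358 min with minimums of 10 and 200 counts. Added scales gave 1.462 min (RNase P RNA) and 1.443 min (signal recognition particle RNA), and the 2 min replicate 2 library 1.43 min as deposited and 1.405 min where it differs (both added). Leaving out a replicate or the 4 min replicate 2 library gave 1.396 to 1.419 min. The rsaA half-life from 0 to 4 min was -23.19 min, no fall. The cause was not tested.

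The mRNA left at 2 min was 55.07% with the replicate 2 library as deposited (added), 54.38% against tRNA, 57.35% against signal recognition particle RNA and 46.94% against RNase P RNA. At 8 min the last 2 gave 10.76% and 11.75%, and at 15 min RNase P RNA gave 6.368%. Single replicates ranged from 59.65% to 74.73% at 1 min, 27.63% to 54.78% at 4 min, 8.945% to 9.492% at 8 min and 4.352% to 5.171% at 15 min.

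Of 105 group tests, 14 passed camera, 0 with an estimated correlation (8 at an unadjusted p under 0.05), 23 on the stable RNA scale and 16 without the 4 min replicate 2 library, the only further library left out in these tests. The count in fry was 73, but fry tests a group against no change and camera against the other genes, so the numbers answer different questions.

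On the stable RNA scale 28 values of named genes that were called higher with TMM turned negative. Values not called with TMM and genes named only as group members were not counted here. At 1 min these were dnaK -0.5765, pnp -0.1674, rsaA -0.09328, fljK -0.5296, rne -0.2427, pilA -0.5421, rpoD -0.1388, acnA -0.3717 and parA -0.1205. At 4 min they were dnaK -1.584, pnp -0.3287, fljK -0.377, rne -2.325, gcrA -1.808, pilA -0.7871, rpoD -1.039 and acnA -1.085. At 15 min they were CCNA_01854 -0.04824, CCNA_00434 -0.7972, CCNA_02930 -0.5132, CCNA_01231 -0.5562, CCNA_01035 -0.7223, pnp -5.397, rsaA -1.147, fljK -2.128, gcrA -4.234, pilA -4.083 and acnA -5.448. On protein-coding totals 5 did: dnaK -0.4153, rne -1.087 and gcrA -0.2905 at 4 min, and pnp -0.9808 and acnA -1.044 at 15 min.

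With the replicate as a block, gcrA at 1 min (0.34, adjusted p = 0.0123, edgeR) and toxin-antitoxin at 2 min (camera) passed, and 15 group tests passed in all. The toxin-antitoxin call rests on 1 library at 2 min, and without the block the group did not pass camera with an estimated correlation. The replicate block gave 2102, 2441, 2623, 1949 and 1606 genes at 1, 2, 4, 8 and 15 min. The half-life median was 1.333 min in the negative binomial fit with this block. The block changed no other call of a named gene or group.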

Other observations

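In this part, the bootstrap interval of the length relation and the 4 and 8 min tests of gene order were chosen after the result was seen. Of 85 non-coding and antisense RNA rows with enough counts for a fit, 30 (35.3%) had over 50% of their level per stable RNA left at 15 min in both replicates, against 6 of 2790 protein-coding genes. The median half-life of the 85 was 6.70 min (6.88 and 7.14 min in the replicates). The small RNAs chvR and gsrN had 78.2% ± 4.10 and 84.1% ± 5.55 left (SD, n = 2). The 6 coding genes, named after their values were seen, were CCNA_02930 (70.2% ± 2.66), CCNA_01231 (69.3% ± 10.5), CCNA_01035 (60.6% ± 0.272), CCNA_02309 (60.1% ± 7.60), CCNA_03965 (54.1% ± 2.75) and btuB (51.2% ± 1.13). The difference between the classes was not tested, and an RNA inside or opposite a stable RNA gene would be counted with it where strand was not used.

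Genes far along the nuo cluster held their level longer at 4 and 8 min, and polymerases that were past the promoter when rifampicin was added may have finished the cluster. This predicts a change that rises with gene order early in the course. Across the 14 nuo genes the rank correlation of gene order with the change was 0.345 at 1 min (permutation adjusted p = 0.300), 0.402 at 2 min (0.247), 0.662 at 4 min (0.0475) and 0.96 at 8 min (0.00016; p = 2e-05 is the smallest the permutations can give), adjusted over 8 tests. Across 26 ribosomal protein cluster genes it was -0.367, 0.0297, 0.215 and 0.344, none past the threshold (permutation adjusted p of 0.173 to 0.884). The prediction for 1 and 2 min was not met in either cluster, and the idea is a hypothesis from the same data. This rank test cannot decide it. At 1 min nuoA (26.0%) and nuoB (63.2%) were low per stable RNA, while nuoC to nuoN lay at 87.6% to 105.2% with little order to rank. In the ribosomal protein cluster the level dipped again far along, with rpsM at 34.9% at 2 min (n = 1), which a single order over the cluster misses. The same idea predicts that long genes are protected at 1 min. Across 1062 genes the rank correlation of length with the change was 0.108 (bootstrap interval 0.0478 to 0.166), above the bound of 0.1 set before the value was seen. The interval, added afterwards, lies on both sides of that bound, which leaves the idea open. At 2, 4 and 8 min the correlation was -0.0545, -0.0967 and -0.0459, opposite in sign.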
